A study of Mus musculus with 18 samples.

How the data were processed

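RNA from the liver of 18 male C57BL/6J mice at 62 weeks of age was measured by the authors on Affymetrix Mouse Genome 430 2.0 arrays, with 3 arrays in each of 6 groups (LF, LF+CR, LF+Ex, HF, HF+CR, HF+Ex), each from another mouse. Per the labels, total RNA was extracted with Trizol and labelled as biotinylated cRNA. The deposited values are intensities per probe set on a linear scale, summarised and scaled between arrays by the authors, and the tool and the method of normalization are not given in the sources used here. The time of day and the fed state at sampling are not given either. The lowest intensity was 31.08 and the highest 21653.9. The medians of the arrays differed by at most 0.15254 on the log2 scale, under the limit of 0.2 set beforehand, so that the values were used as deposited, as log2 of the intensity plus 16.

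Of 45101 probe sets, 64 controls were left out. Of the other 45037, 34945 carried 1 gene symbol, 932 several and 9160 none, and those with several were not used. Genes were represented by the probe set with the highest mean (18193 genes). A gene was tested if its probe set lay above the 40th percentile of an array, which fell between intensities of 88.22 and 97.574, on at least 3 arrays. This left 14201 genes and removed 3992. Probe sets of families such as Cyp2b, Mup, Gstm and Slc22a can share sequence, and probe sequences were not used here. For arrays the depth is the signal over background, and the number of arrays limits the precision.

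A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (12 residual and 3.64 prior degrees of freedom). It gave 7 comparisons of a pair of groups and 2 interactions, each with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Values are means ± SD of 3 arrays, and SE is the moderated standard error of the log2 fold change. The model does not pair the arrays, because their replicate numbers do not mark pairs. In the text, adjusted p without another name comes from camera for lists and from limma for genes.

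Before the data were examined, 45 gene lists (28 pathways and 17 cell types, 773 genes) were fixed, and each was tested with camera with a preset correlation of 0.01 and with an estimated correlation, and with fry. For 73 of these genes no probe set carried the symbol alone, 33 were too dim, and 29 were in more than 1 list. The genes named in the text follow a rule fixed at the same time: the 5 largest rises and falls among changed genes whose groups do not overlap, up to 4 changed members (2 where this gave over 30 genes) of each list with at least 3 changed members or called by camera, and the genes that passed from a fixed set of 30, of which 26 were measured. Genes named beside a small count outside this rule were chosen after their values were seen. For 111 of 223 such pairs of gene and comparison another probe set of the gene lay above the 40th percentile on at least 3 arrays. In 7 of these every such probe set moved under 25% as far, but in 4 of the 7 its mean did not exceed the highest dim threshold, so that it could hardly show a change.

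Alternatives were quantile normalization, arrays centred on their median, offsets of 1 and 64, no filter on dim genes or one at the 60th percentile, the mean of the probe sets of a gene, a trended robust variance, array weights, a fit of the compared groups only, the replicate number as a block, and each array left out in turn. After the data had been seen, fits without 3 arrays, without 4 other arrays and with a clock covariate were added. Fold changes that share a control group were compared with 100 simulations of unchanged groups. The pipeline was tested on simulated data with 200 changed genes in 20 runs. It recovered 76.6% of changes of 0.5 on the log2 scale and 95.9% of changes of 1, with 4.99% false calls. The simulated genes were independent and the simulated arrays of equal quality, so that these rates may differ on the real arrays.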

Results

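Liver RNA of male C57BL/6J mice, an inbred laboratory strain, was measured at 62 weeks of age on 18 Affymetrix Mouse Genome 430 2.0 arrays, with 3 mice in each of 6 groups. Mice ate a low-fat diet (LF, 10% fat) or a high-fat diet (HF, 60% fat) without limit, ate the same diet with 30% calorie restriction (LF+CR and HF+CR), or ate it without limit and had a running wheel (LF+Ex and HF+Ex), from the age of 5 weeks. The design asks how dietary fat, calorie restriction and voluntary running each set liver gene expression late in life, and whether the effect of either intervention depends on the diet. Values were intensities per probe set, from 31.08 to 21653.9, with array means between 304.9 and 307.8. 14201 genes were tested. The number of arrays limited the precision, and the median standard error of a log2 fold change was 0.0853 for a pair of groups and 0.121 for an interaction.

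The arrays differed in ways that the groups did not explain. On the first principal component, which held 27% of the variance, LF+CR 2 (23.6), HF 1 (21.1) and HF+Ex 3 (19.1) lay farthest out, and HF 1 and HF+Ex 3 were the most similar pair of arrays (r = 0.995), although they belong to different groups. Pancreatic digestive enzyme transcripts stood out on 4 arrays. Clps, which encodes colipase, read 260 on LF 1, 386 on LF+CR 1, 215 on LF+Ex 3 and 599 on HF+Ex 1, against 52.6 to 62.1 on the other arrays. The clock genes also differed between mice of a group: log2 Arntl minus log2 Dbp, genes of opposite daily phase, was -0.66 on LF+Ex 3, -1.88 on LF 1, -2.13 on HF+CR 3 and -2.57 on LF+CR 2, and lay between -4.32 and -2.84 elsewhere. Counts without these arrays, or with the clock difference as a covariate, stand with each comparison where they moved it by over 1.5 times. These settings were chosen after the data had been seen. Group means under the dim threshold of an array (88.22 to 97.574) were not above background. A log2 fold change against such a group depends on the background and on the offset, and is given below with the values at offsets of 1 and 64 where the gene opens a comparison. Of 223 named pairs of gene and comparison 25 had such a group, and all 25 passed with both offsets.

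**Figure D1:**
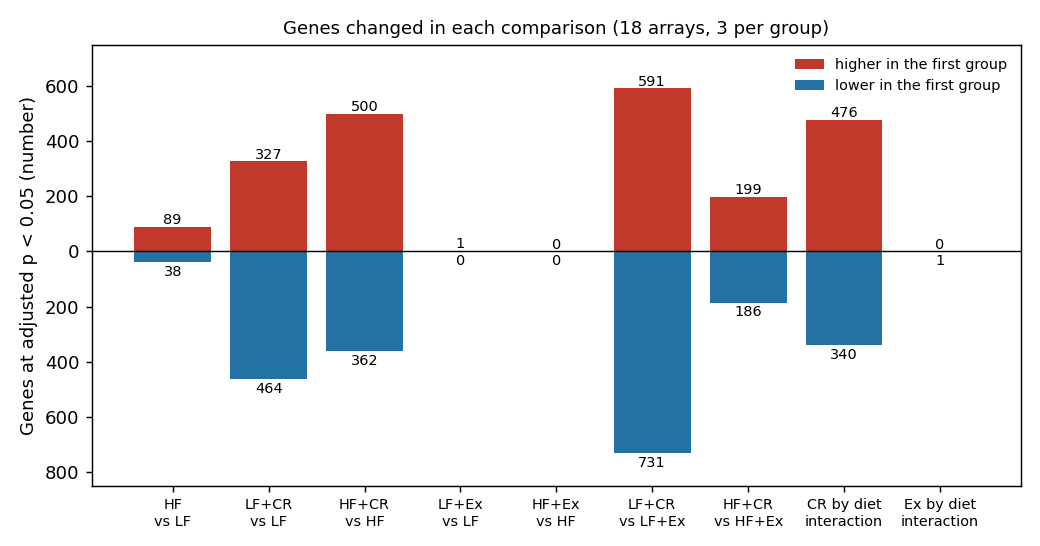
Number of genes changed (limma, adjusted p under 0.05) in each of the 7 comparisons of a pair of groups and the 2 interactions, with genes higher in the first group above 0 and genes lower in it below 0, 3 arrays per group. The counts were 385 or more where calorie restriction was compared with any other group, and 1, 0 and 1 for exercise on LF, exercise on HF and the exercise by diet interaction.

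The first comparison asked what long-term dietary fat did without any intervention. In HF livers, 4 of 21 lipid droplet genes rose and 4 of 18 male-biased genes fell, and neither list was called with an estimated correlation (adjusted p = 0.253 and 0.163). Cidea, which encodes a lipid droplet protein, was at 973 ± 475 in HF and 95.8 ± 20.001 in LF (n = 3 each), a log2 fold change of 3.05 (SE 0.404; 3.23 and 2.60 at offsets of 1 and 64, since the LF mean is near background), and Plin4, Mogat1 and Pparg rose with it by 1.09, 0.89 and 0.91. The male-typical steroid enzyme gene Hsd3b5 fell from 1021 ± 855 to 72.9 ± 2.58, which is at background (log2 -3.11, SE 0.545; -3.34 and -2.61 at offsets of 1 and 64). Slco1a1, an organic anion uptake transporter, fell from 1523 ± 507 to 110 ± 7.46 (log2 -3.56, SE 0.375). The female-typical cytochromes Cyp2b9 and Cyp2b13 rose by 2.70 and 1.97, the latter from a mean at background. In all, 127 of 14201 genes changed, 89 higher and 38 lower (limma, adjusted p under 0.05).

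Of the lists fixed beforehand, 4 of 21 lipid droplet and fatty acid uptake genes rose and none fell over all genes tested, with 9 higher and 0 lower when adjusted over the list alone (camera adjusted p = 4.19e-06 with the preset correlation, adjusted p = 0.253 with an estimated correlation). Of 18 male-biased genes 4 fell, among them C8b (log2 -1.21), and 9 fell when adjusted over the list alone (camera adjusted p = 1.19e-08, adjusted p = 0.163 with an estimated correlation). Of 18 female-biased genes 4 rose, including the transporter Slc22a27 (log2 1.63), and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.262 with an estimated correlation). In the growth hormone, insulin and IGF1 list, 2 of 19 genes fell: Socs2, a feedback inhibitor of growth hormone signalling (log2 -1.93, SE 0.357), and the receptor gene Egfr (log2 -1.76, SE 0.339). When adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 0.0115, adjusted p = 0.505 with an estimated correlation). Msmo1 (log2 1.35) and Insig1 (log2 0.48) were the 2 of 19 cholesterol synthesis genes that rose, with 7 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.000852, adjusted p = 0.558 with an estimated correlation). Gsta2, a glutathione transferase gene (log2 1.596), the pericentral glutamine synthetase gene Glul (log2 0.35) and the fatty acid synthase gene Fasn (log2 0.83, SE 0.188) also rose, and Fabp5, a fatty acid binding protein gene, fell by 2.17 on the log2 scale. None of the 45 lists was called with an estimated correlation, and 22 of the 26 measured genes of the fixed set did not pass.

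The count depended on single arrays: it was 34 without LF 1, 52 without LF 3, 23 without HF 1, 200 without HF 2 and 24 without HF 3. It was 988 with array weights and 60 when only these 6 arrays were fitted. Without the 4 arrays that carried pancreatic transcripts it was 13, and with the clock covariate 231.

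Calorie restriction on the low-fat diet was compared next. Lipid synthesis genes rose and sex-biased genes moved away from the male pattern. The fed state at sampling is not given and may differ between restricted and unrestricted mice, on this diet and on the high-fat diet. Its part in these changes was not tested. Sqle, which encodes squalene epoxidase of cholesterol synthesis, rose from 177 ± 60.1 in LF to 1095 ± 5.53 in LF+CR (n = 3 each; log2 2.57, SE 0.304), Fasn rose from 655 ± 138 to 3947 ± 1017 (log2 2.55, SE 0.188) and Acly, the source of cytosolic acetyl-CoA, rose by 2.08 (SE 0.143). Elovl3, a male-biased fatty acid elongase gene, fell from 2847 ± 384 to 188 ± 113 (log2 -3.98, SE 0.465), Slco1a1 fell by 3.68 and Hsd3b5, to a mean at background, by 3.11 on the log2 scale, and Cyp2b9 rose from 282 ± 131 to 2482 ± 770 (log2 3.10, SE 0.267). In all, 791 genes changed, 327 higher and 464 lower, and 779 of them had groups that did not overlap (20.2% of all genes did not, against 10% by chance for 3 against 3).

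Of 19 cholesterol synthesis genes 15 rose and none fell, among them Idi1 (log2 2.58), Pmvk (log2 1.36) and Lss (log2 1.19), and 17 rose when adjusted over the list alone (camera adjusted p = 2.11e-29, adjusted p = 0.0105 with an estimated correlation). Of 22 fatty acid and triglyceride synthesis genes 13 rose and 2 fell, with 15 and 2 when adjusted over the list alone (adjusted p = 0.0446 with an estimated correlation). Srebf1, the transcription factor gene of that programme, rose by 1.23 (SE 0.195), and the genes that fell were Mlxipl (log2 -0.67), which encodes the carbohydrate-responsive factor ChREBP, and Agpat2 (log2 -0.52). Of 18 male-biased genes 11 fell and none rose, 12 when adjusted over the list alone, and of 18 female-biased genes 5 rose and none fell, 8 when adjusted over the list alone (adjusted p = 0.0105 with an estimated correlation for both lists). The male-biased cytochrome gene Cyp4a12a fell by 3.03 and the oxysterol hydroxylase gene Cyp7b1 by 1.77 on the log2 scale. The urinary protein gene Mup10, which is in no list, fell by 2.90.

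Fatty acid breakdown and storage lists moved down without holding under an estimated correlation. Of 18 peroxisomal and microsomal oxidation genes 7 fell, led by Vnn1 (log2 -1.47), and 10 fell and 1 rose when adjusted over the list alone (adjusted p = 0.113 with an estimated correlation). Of 21 lipid droplet genes 7 fell, for example Fitm2 (log2 -0.62), and 8 fell and 1 rose when adjusted over the list alone (adjusted p = 0.268 with an estimated correlation). Of 19 mitochondrial oxidation genes 5 fell, including Cpt1a, the gate of mitochondrial fatty acid entry (log2 -0.48), and 6 fell when adjusted over the list alone (adjusted p = 0.466 with an estimated correlation). In the other direction, 6 of 16 xenobiotic P450 genes rose, 8 when adjusted over the list alone (adjusted p = 0.113 with an estimated correlation), and 7 of 21 NRF2 and glutathione genes rose, 11 when adjusted over the list alone (adjusted p = 0.466 with an estimated correlation). Gstm3 of that list was at 5641 ± 3703 in LF+CR, and LF+CR 2 alone read 9870. Of 14 glycolysis and glycogen genes 5 rose, such as Pgk1 (log2 0.36) and Gbe1 (log2 0.61), with 7 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0592 with an estimated correlation). Of 26 measured genes of the fixed set 20 did not pass. The count of changed genes was 477 without LF 3, 446 without LF+CR 1, 1435 with array weights and 189 when only these 6 arrays were fitted. It was 240 without the 4 arrays with pancreatic transcripts.

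With calorie restriction on the high-fat diet cholesterol synthesis genes were higher too, lipid droplet genes were lower, and sex-biased genes lay nearer the male pattern. Sqle rose from 299 ± 149 in HF to 1079 ± 199 in HF+CR (n = 3 each; log2 1.92, SE 0.304). Cidea fell from 973 ± 475 to 75.1 ± 10.8, which is at background (log2 -3.33, SE 0.404; -3.57 and -2.80 at offsets of 1 and 64). The fatty acid transporter gene Cd36 fell from 2431 ± 368 to 736 ± 143 (log2 -1.71, SE 0.180), and Cidec (to background), Plin4 and Apoa4 fell by 2.00, 1.38 and 1.99 on the log2 scale. Hsd3b5 rose from 72.9 ± 2.58, at background, to 3271 ± 820 (log2 5.18, SE 0.545; 5.44 and 4.58 at offsets of 1 and 64), Slco1a1 rose from 110 ± 7.46 to 2450 ± 54.2 (log2 4.29, SE 0.375), and Egfr rose by 2.40. In all, 862 genes changed, 500 higher and 362 lower, and with each array centred on its median the split was 373 higher and 424 lower.

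Of 19 cholesterol synthesis genes 15 rose and none fell, 18 when adjusted over the list alone, and of 21 lipid droplet genes 10 fell and none rose, 12 when adjusted over the list alone (camera adjusted p = 0.0423 with an estimated correlation for both). The same adjusted p held for 3 other lists. Of 18 male-biased genes 9 rose, 12 when adjusted over the list alone. Of 18 female-biased genes 5 fell, such as Slc22a27 (log2 -2.27) and Cyp2b13 (log2 -1.85, to background), and 5 fell when adjusted over the list alone. Of 18 peroxisomal and microsomal oxidation genes 7 fell, led by Pex11a, a peroxisome proliferation factor (log2 -1.25), and 10 fell when adjusted over the list alone. Of 16 xenobiotic P450 genes 7 fell, among them Cyp2c38 (log2 -1.65), with 1 higher and 9 lower when adjusted over the list alone (adjusted p = 0.0457 with an estimated correlation). Of 22 fatty acid synthesis genes 3 rose, Acly (log2 0.93), Acss2 (log2 0.96) and Slc25a1 (log2 0.22), and 4 rose when adjusted over the list alone (camera adjusted p = 0.489, adjusted p = 0.950 with an estimated correlation), while Fasn stood at 1764 ± 87.1 in HF+CR and 1180 ± 232 in HF (adjusted p = 0.0749).

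Immune and stress genes moved in part. Of 24 interferon response genes 4 fell, including Ifit3 (log2 -0.48) and Rsad2 (log2 -0.90), with 2 higher and 9 lower when adjusted over the list alone (adjusted p = 0.42 with an estimated correlation). No Kupffer cell marker passed over all genes tested, and 6 of 12 were lower when adjusted over the list alone (median log2 -0.54, adjusted p = 0.42 with an estimated correlation). Of 22 autophagy and lysosome genes 3 fell, such as the hexosaminidase gene Hexa (log2 -0.72), with 1 higher and 8 lower when adjusted over the list alone (adjusted p = 0.0662 with an estimated correlation). Of 25 endoplasmic reticulum chaperone genes 5 rose, among them Calr (log2 0.55), with 9 higher and 1 lower when adjusted over the list alone (adjusted p = 0.456 with an estimated correlation). Pdia6 of that list rose by 0.69. Rad51b, a DNA repair gene, fell by 2.53 on the log2 scale. Lgals1, which encodes galectin-1, fell by 2.30, and Igfbp2 rose by 0.77. Of 26 measured genes of the fixed set 18 did not pass.

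The count was 284 without HF 1, 410 without HF 3, 365 without HF+CR 1 and 343 without HF+CR 2, and 2174 with array weights. It was 549 without the 3 arrays far out on the first component, 517 without the 4 arrays with pancreatic transcripts and 1374 with the clock covariate.

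**Figure D2:**
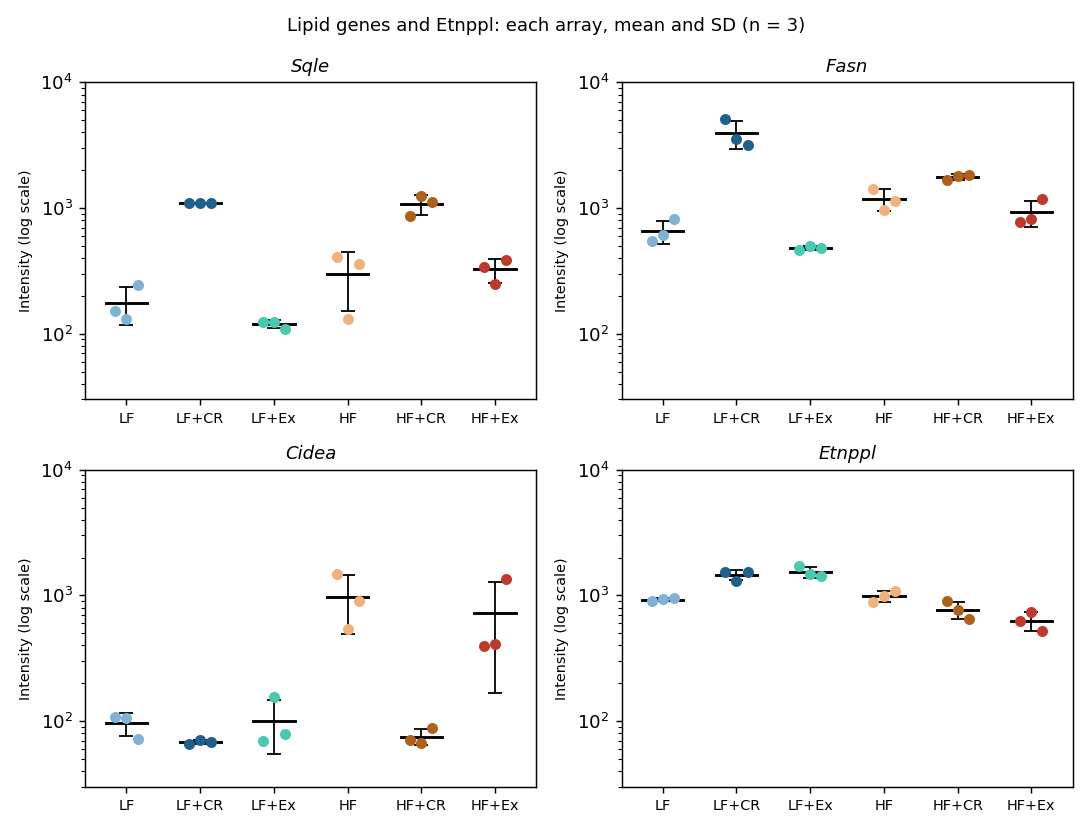
Intensity (log axis) of Sqle, Fasn, Cidea and Etnppl on each of the 18 arrays, with the mean as a bar and the SD as an error bar (n = 3 per group). Sqle averaged 1095 in LF+CR and 1079 in HF+CR against 299 in HF and 177 in LF, and Cidea averaged 973 in HF against 75.1 in HF+CR.

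Voluntary running was compared with the sedentary group on each diet. Hardly any single gene changed. On the low-fat diet 1 gene rose, Abhd13, which encodes a protein of the alpha/beta hydrolase family, from 286 ± 16.1 in LF to 402 ± 14.1 in LF+Ex (n = 3 each; log2 0.47, SE 0.0651, limma adjusted p = 0.0309). Its other probe sets had log2 fold changes of 0.15, 0.10 and 0.02. In the mean over its probe sets this gene no longer passed, and the count was 0 without LF 1, LF 2, LF 3, LF+Ex 1, LF+Ex 2 or LF+Ex 3. On the high-fat diet limma called 0 genes, with 348 at an unadjusted p under 0.05, where 710 would be due to chance for independent genes. The corresponding number on the low-fat diet was 561. With array weights these numbers were 1271 on the high-fat and 1258 on the low-fat diet, and without LF 1 the latter was 980. A number below 710 therefore depends on how the arrays are weighted. Groups did not overlap for 8.82% of genes on LF and 8.12% on HF, against 10% by chance.

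Some fixed lists shifted as a whole under the preset correlation, and none of the 45 on either diet was called with an estimated one. In HF+Ex the 25 endoplasmic reticulum chaperone genes had a median log2 fold change of 0.25, with 0 passing over all genes tested and 13 higher when adjusted over the list alone (camera adjusted p = 1.84e-20, adjusted p = 0.102 with an estimated correlation). The 20 heat shock genes had a median of 0.19, with 4 higher when adjusted over the list alone (adjusted p = 0.0858 with an estimated correlation). In LF+Ex the medians of the same lists were 0.16 and 0.12 (adjusted p = 0.263 and 0.246 with an estimated correlation). Male-biased genes had medians of 0.38 in LF+Ex and 0.34 in HF+Ex, with 5 and 0 of 18 higher when adjusted over the list alone (adjusted p = 0.246 and 0.173 with an estimated correlation). Slco1a1 stood at 331 ± 237 in HF+Ex and 110 ± 7.46 in HF, and at 2345 ± 271 in LF+Ex and 1523 ± 507 in LF, none of which passed. Pancreatic acinar markers had a median of 0.65 in HF+Ex (adjusted p = 0.609 with an estimated correlation), and 0.02 without the 4 arrays that carried such transcripts. None of the 26 measured genes of the fixed set passed on either diet. The LF+Ex count was 7 with array weights, 2 with a trended robust variance, 6 without the 3 arrays far out on the first component, and 0 with centred arrays, with the mean of probe sets, with only the 6 arrays fitted, without the arrays with pancreatic transcripts or with the clock covariate. The HF+Ex count was 1 without HF+Ex 3.

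Calorie restriction and running were then compared with each other on the low-fat diet. Cyp2b9 was at 2482 ± 770 in LF+CR and 81.0 ± 17.4, at background, in LF+Ex (n = 3 each; log2 4.65, SE 0.267; 4.89 and 4.09 at offsets of 1 and 64), Fasn at 3947 ± 1017 and 484 ± 18.2 (log2 2.96, SE 0.188), and Sqle at 1095 ± 5.53 and 119 ± 8.67 (log2 3.04, SE 0.304). Elovl3, Slco1a1 and Hsd3b5 were lower in LF+CR, with log2 fold changes of -4.40, -4.34 and -3.96, the last against a mean at background. In all, 1322 genes differed, 591 higher and 731 lower in LF+CR.

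Of 19 cholesterol synthesis genes 17 were higher in LF+CR, 18 when adjusted over the list alone (adjusted p = 0.0116 with an estimated correlation). Fdps and Sc5d were higher by 2.97 and 1.08, and the other probe sets of Sc5d had log2 fold changes of 0.06 and 0.09. Of 18 male-biased genes 13 were lower, 13 when adjusted over the list alone, and of 18 female-biased genes 8 were higher, 11 when adjusted over the list alone (adjusted p = 0.00866 with an estimated correlation for both). Of 22 fatty acid synthesis genes 13 were higher and 2 lower, 16 and 2 when adjusted over the list alone (adjusted p = 0.0580 with an estimated correlation). Of 18 peroxisomal oxidation genes 8 were lower and 1 higher, 10 and 1 when adjusted over the list alone (adjusted p = 0.220 with an estimated correlation), and of 21 lipid droplet genes 7 were lower, led by Fitm2 (log2 -0.65) and Plin5 (log2 -1.24), and 2 higher, with 8 and 2 when adjusted over the list alone (adjusted p = 0.325 with an estimated correlation). Of 20 heat shock genes 7 were lower and 1 higher, for example Hspa8 (log2 -0.43), with 8 and 1 when adjusted over the list alone (adjusted p = 0.319 with an estimated correlation). Among the smaller groups, 3 of 27 acute phase genes were lower, including Saa4 (log2 -1.13), with 3 when adjusted over the list alone (camera adjusted p = 0.796), and 2 of 16 cell cycle genes were higher, Mcm3 (log2 0.31) and Mki67 (log2 0.35), with 3 when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Pimreg was at 67.2 ± 10.6, at background, in LF+CR and 806 ± 215 in LF+Ex (log2 -3.28; -3.55 and -2.70 at offsets of 1 and 64). Of 26 measured genes of the fixed set 19 did not pass.

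The count was 801 without LF+Ex 1, 872 without LF+Ex 3, 827 without LF+CR 1, 2539 with array weights and 532 when only these 6 arrays were fitted. Without the 4 arrays with pancreatic transcripts it was 468.

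On the high-fat diet, the same comparison of restriction with running gave higher cholesterol synthesis and lower lipid storage expression in HF+CR. Hsd3b5 was at 3271 ± 820 in HF+CR and 106 ± 46.8 in HF+Ex (n = 3 each; log2 4.79, SE 0.545), Slco1a1 was higher by 3.11 (SE 0.375), and Idi1 and Sqle were both higher by 1.69. Hsd3b5 was at background on HF+Ex 1 (79.9) and HF+Ex 3 (77.8), so that its log2 fold change depends on the offset. Cidea was at 75.1 ± 10.8, at background, and 721 ± 554 (log2 -2.78, SE 0.404; -3.00 and -2.28 at offsets of 1 and 64), and Cd36 at 736 ± 143 and 2225 ± 428 (log2 -1.58, SE 0.180). In all, 385 genes differed, 199 higher and 186 lower in HF+CR, and with each array centred on its median the split was 103 higher and 225 lower.

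Of 19 cholesterol synthesis genes 14 were higher, 18 when adjusted over the list alone (adjusted p = 0.0417 with an estimated correlation). Of 21 lipid droplet genes 9 were lower, 12 when adjusted over the list alone, of 18 peroxisomal oxidation genes 6 were lower, 10 when adjusted over the list alone, and of 18 female-biased genes 4 were lower, 5 when adjusted over the list alone (adjusted p = 0.0261 with an estimated correlation for the 3 lists). Of 16 xenobiotic P450 genes 5 were lower and 1 higher, 8 and 1 when adjusted over the list alone (adjusted p = 0.0445 with an estimated correlation), with Alas1, which encodes the first enzyme of heme synthesis, at a log2 fold change of -1.19. Of 18 male-biased genes 6 were higher, 13 when adjusted over the list alone (camera adjusted p = 1.37e-07, adjusted p = 0.0524 with an estimated correlation). Of 22 fatty acid synthesis genes 5 were higher, among them Acly (log2 1.01), Fasn (log2 0.94) and Srebf1 (log2 0.98), and 6 when adjusted over the list alone (adjusted p = 0.743 with an estimated correlation). Apoa4, Cidec (against background) and Nampt, the last a gene of NAD salvage, had log2 fold changes of -1.65, -1.90 and -0.80, and 16 of the 26 measured genes of the fixed set did not pass. The count was 131 without HF+Ex 1, 125 without HF+Ex 3, 157 without HF+CR 1, 170 without HF+CR 2, 1067 with array weights and 93 when only these 6 arrays were fitted. It was 191 without the 3 arrays far out on the first component, 39 without the 4 arrays with pancreatic transcripts and 848 with the clock covariate.

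Whether the diet altered the effect of calorie restriction was tested as an interaction, the change on the high-fat diet minus that on the low-fat diet. Sex-biased genes gave the largest differences, because they moved in opposite directions on the 2 diets. Hsd3b5, at background in LF+CR and HF, had an interaction of 8.29 (SE 0.771; 8.78 and 7.19 at offsets of 1 and 64), Slco1a1 of 7.96 (SE 0.530) and Elovl3 of 5.44 (SE 0.658), while Cyp2b13, Slc22a27 and Cyp2b9 had interactions of -4.52, -4.51 and -4.41. Cyp2b13 was at background in LF and HF+CR. Single genes of fat metabolism differed as well: Fasn (log2 -1.96, SE 0.266) and Acly (log2 -1.16, SE 0.202) were raised more on the low-fat diet, and Cd36 (log2 -1.92, SE 0.254) and Pparg (log2 -1.65, SE 0.243) were lowered on the high-fat diet, with Cd36 at 1574 ± 113 in LF and 1835 ± 301 in LF+CR. In all, 816 genes had an interaction, 476 positive and 340 negative.

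Of 18 male-biased genes 13 had a positive interaction and none a negative one, 14 when adjusted over the list alone (camera adjusted p = 4.24e-17, adjusted p = 0.00646 with an estimated correlation). Of 18 female-biased genes 6 were negative, 11 when adjusted over the list alone (adjusted p = 0.00602 with an estimated correlation). Of 16 xenobiotic P450 genes 7 were negative, with 1 positive and 8 negative when adjusted over the list alone, and of 14 glycolysis and glycogen genes 5 were negative, including Gbe1 (log2 -1.13) and Pgk1 (log2 -0.42), with 2 positive and 7 negative when adjusted over the list alone (adjusted p = 0.0236 with an estimated correlation for both). Of 22 fatty acid synthesis genes 6 were negative and 1 positive, 12 and 1 when adjusted over the list alone (adjusted p = 0.207 with an estimated correlation). Of 21 lipid droplet and fatty acid uptake genes 4 were negative and 2 positive, 8 and 2 when adjusted over the list alone (adjusted p = 0.524 with an estimated correlation). Of 21 NRF2 and glutathione genes 9 were negative, such as Gsta2 (log2 -2.72) and Nqo1 (log2 -2.13), and 13 when adjusted over the list alone (adjusted p = 0.375 with an estimated correlation). Nqo1 was at 617 on LF+CR 2 against 287 and 240 on the other LF+CR arrays. Cholesterol synthesis genes had 1 negative interaction of 19, Insig1 (log2 -0.78), and 1 when adjusted over the list alone (adjusted p = 0.575 with an estimated correlation). In the growth hormone list 4 of 19 were positive, among them Egfr (log2 3.33) and Igf1 (log2 0.55), and 4 when adjusted over the list alone (adjusted p = 0.549 with an estimated correlation). Stat2 and Etnppl, with interactions of 0.32 and -0.998, each had another probe set above the dim threshold (mean intensities of 183 and 163), with interactions of -0.10 and -0.16. Both means lie under the bound of 195 applied to other genes below. Rad51b had an interaction of -3.58. Of 26 measured genes of the fixed set 19 did not pass. The count was 524 without LF 3, 520 without LF+CR 2, 386 without HF 1 and 1592 with array weights. It was 371 without the 3 arrays far out on the first component, 287 without the 4 arrays with pancreatic transcripts and 1391 with the clock covariate.

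**Figure D3:**
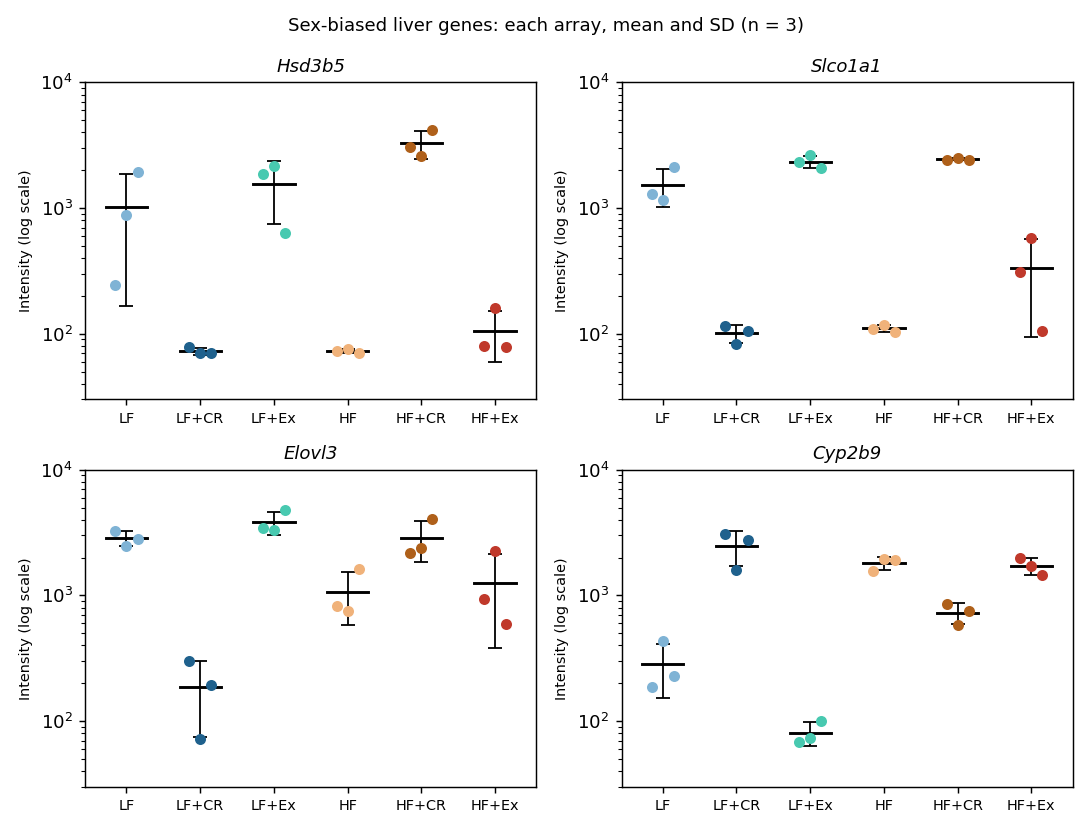
Intensity (log axis) of the male-biased genes Hsd3b5, Slco1a1 and Elovl3 and the female-biased gene Cyp2b9 on each of the 18 arrays, with the mean as a bar and the SD as an error bar (n = 3 per group). Hsd3b5 averaged 72.9 in both LF+CR and HF against 1021 in LF and 3271 in HF+CR.

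The exercise by diet interaction was passed by 1 gene, Etnppl, a periportal gene that encodes ethanolamine-phosphate phospho-lyase. It was at 1536 ± 150 in LF+Ex and 927 ± 28.4 in LF, and at 630 ± 109 in HF+Ex and 986 ± 100 in HF (n = 3 each; interaction log2 -1.36, SE 0.180, limma adjusted p = 0.0189). Its other probe set above the dim threshold, at a mean intensity of 163, had an exercise interaction of -0.50, and in the mean over its probe sets the gene did not pass. 358 genes had an unadjusted p under 0.05, and 1266 with array weights. None of the 45 lists was called with an estimated correlation (smallest adjusted p = 0.220). The count was 0 without LF 1, LF 2, LF 3, LF+Ex 1, LF+Ex 2, HF 2, HF 3, HF+Ex 1 or HF+Ex 3, and 2 with array weights. It was 0 with quantile normalization, with the mean of probe sets and without the 4 arrays with pancreatic transcripts.

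**Figure D4:**
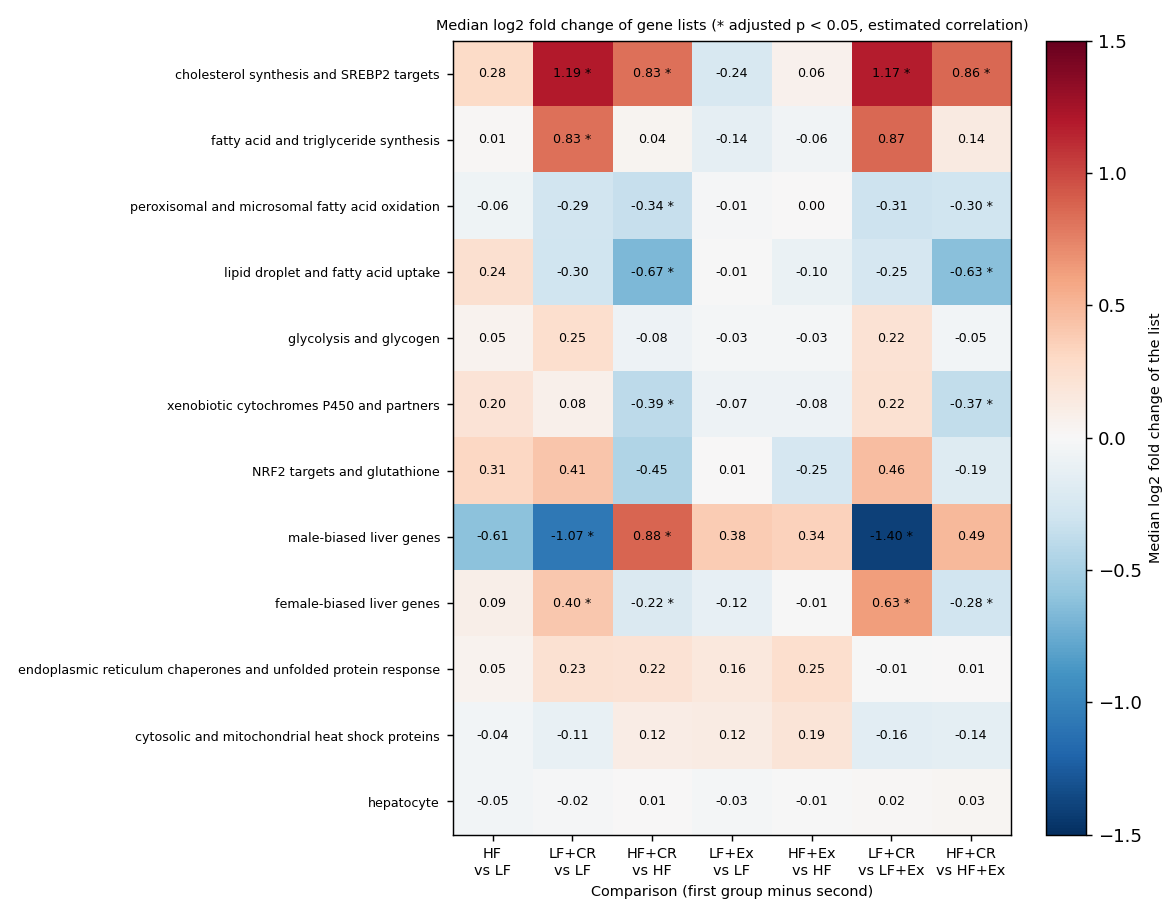
Median log2 fold change of 12 gene lists (vertical axis) in the 7 comparisons of a pair of groups (horizontal axis, first group minus second), where an asterisk marks lists with a camera adjusted p under 0.05 with an estimated correlation. Male-biased genes had a median of -1.07 in LF+CR vs LF and 0.88 in HF+CR vs HF, and cholesterol synthesis genes 1.19 and 0.83.

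Fold changes were compared across the 14201 genes, which are not independent replicates. The effects of restriction on the 2 diets, which share no arrays, correlated with r = -0.18 (jackknife SE 0.197, -0.24 without LF+CR 3 to -0.01 without LF+CR 2, simulated mean -0.001). The similarity of fold changes, LF+CR vs LF with HF+CR vs HF, was 0.00413 without the 3 arrays far out on the first component, so that its sign is not settled. 387 of the 791 genes changed on LF had the opposite sign on HF. Of the genes changed on both diets, 51 were higher on both (11.5 for independent lists), 43 lower on both (11.8), 28 higher on LF and lower on HF (8.34), and 45 lower on LF and higher on HF (16.3). Exercise on the 2 diets gave r = 0.12 (jackknife SE 0.123), between 0.03 without LF+Ex 2 and 0.17 without LF+Ex 1. The HF effect and the effect of restriction on HF share the HF arrays, and gave r = -0.68 where unchanged groups gave -0.50 by simulation (covariance -0.0319 against -0.00778), and 116 of the 127 genes changed in HF vs LF (91.3%) had the opposite sign in HF+CR vs HF. With unchanged groups, 95.1% of the 127 genes with the largest simulated effects did so. The simulated HF groups carried no effect, while the 127 real genes were called as changed. The simulation therefore cannot tell how much of the 91.3% comes from the shared arrays. 48 genes were higher and then lower (2.27 for independent lists) and 24 lower and then higher (1.34), together 72, where simulated lists of the same sizes from unchanged groups gave 40.2 on average and at most 56. In HF+Ex vs HF 102 of the 127 genes (80.3%) had the opposite sign, against 95.2% by simulation. HF vs LF with HF+Ex vs HF gave r = -0.41 (jackknife SE 0.366, simulated -0.50, covariance -0.00845 against -0.00780), between -0.60 without HF 2 and -0.16 without HF+Ex 2. LF+CR vs LF with LF+Ex vs LF gave r = -0.13 (jackknife SE 0.203, simulated 0.50, covariance -0.00320 against 0.00775), and r was 0.07 without LF 1 and 0.01 without LF 3. HF+CR vs HF with HF+Ex vs HF gave r = 0.44 (jackknife SE 0.352, simulated 0.50, covariance 0.0112 against 0.00781), between 0.16 without HF+Ex 2 and 0.57 without HF 2. The shared arrays of 3 could not be split into parts of 2, so part of these values may come from them.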

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

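Among the tests in this part, the comparison of lipid droplet genes between LF+CR and HF, the clock covariate and the fits without the arrays that carried pancreatic transcripts were chosen after the data had been seen. The other tests were set before their results were seen.

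The effect of calorie restriction differed between the diets by a test of the interaction (HF effect minus LF effect) for 816 genes. The largest positive interactions were those of Hsd3b5 (8.29), Slco1a1 (7.96), Elovl3 (5.44), Pimreg (4.25) and Mup10 (4.04), and the largest negative ones those of Cyp2b13 (-4.52), Slc22a27 (-4.51), Cyp2b9 (-4.41), Rad51b (-3.58) and Tceal8 (-3.08). Hsd3b5, Pimreg, Cyp2b13 and Cidea had group means at background, so that their values depend on the offset. Slco1a1 lay just above background in LF+CR (101 ± 17.1) and HF (110 ± 7.46), so that its value depends on the offset as well. In lipid and sugar metabolism the interaction was -0.78 for Insig1, -1.96 for Fasn, -1.16 for Acly, -0.89 for Abcd2, 0.49 for Eci2, -1.92 for Cd36, -1.65 for Pparg, -2.94 for Cidea, -1.13 for Gbe1 and -0.42 for Pgk1. Bile acid, detoxification and antioxidant genes had values of 3.17 for Cyp7b1, -2.72 for Gsta2, -2.13 for Nqo1, -0.79 for Prdx3 and 0.44 for Prdx4. Signalling and stress genes had 3.33 for Egfr, 0.55 for Igf1, -0.46 for Hspa9, 0.42 for Ahsa1 and 0.32 for Stat2. Mitochondrial, lysosomal and other metabolic genes had -0.26 for Uqcrfs1, -0.27 for Ndufv1, -0.71 for Ctsd, -0.37 for Ctsb, -0.998 for Etnppl, -1.78 for Aldh1b1 and -1.07 for Nampt.

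By camera with the preset correlation, 18 lists had an interaction of restriction and diet, and 4 of them (male-biased, female-biased, xenobiotic P450, glycolysis) also had one with an estimated correlation. Their median interactions on the log2 scale were 2.08, -0.77, -0.59 and -0.27. The other medians were -0.36 for cholesterol synthesis, -0.69 for fatty acid synthesis, -0.0627 for lipid droplet, -0.74 for NRF2, -0.17 for antioxidant, 0.19 for the growth hormone axis, -0.0271 for oxidative phosphorylation, -0.35 for interferon, -1.18 for MHC class II, -0.23 for extracellular matrix, -0.14 for cell cycle, -0.14 for autophagy and lysosome, -0.72 for Kupffer cell and -0.44 for recruited macrophage genes.

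The exercise by diet interaction was passed by 1 gene, Etnppl (-1.36), and by 7 lists with the preset correlation and 0 with an estimated one. In limma 358 genes had an unadjusted p under 0.05, and 1266 with array weights. The list medians were 0.22 for cholesterol synthesis, -0.26 for NRF2, 0.18 for female-biased, 0.15 for interferon, -0.12 for urea cycle, -0.21 for periportal and 0.99 for pancreatic acinar genes. Probe sets without a gene symbol, which the report does not use, also passed: of 4855 tested, 32 in HF vs LF, 140 in LF+CR vs LF, 217 in HF+CR vs HF, 1 in LF+Ex vs LF, 292 in LF+CR vs LF+Ex, 61 in HF+CR vs HF+Ex, 208 in the calorie restriction by diet interaction and 1 in the exercise by diet interaction.

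As a list, male-biased genes moved in opposite directions under calorie restriction on the 2 diets. All 18 interactions were above 0 (lowest 0.0581, median 2.08), which alone does not show that each gene changed direction. The lowest median with 1 of the 12 arrays left out was 1.96 (without LF+CR 2), which argues against a single array as the source. Hepatocyte markers had a median interaction of 0.0614 (SD 0.207, 13 genes), far below 2.08. This argues against a changed share of hepatocytes as the source, but does not show that the share was unchanged. With the clock covariate the median of the male-biased genes was 2.10, and at least 2.03 with any 1 of the 18 arrays left out, while the count of genes with an interaction moved from 816 to 1391, which argues against clock phase as the whole source. The lipid droplet genes were lower in LF+CR than in HF for 21 of 21 genes (median -0.48), but the interaction is the same with these labels exchanged, so that this says nothing about its source, and other exchanges were not tested. An effect of diet and restriction themselves stays open as untested, as does the fed state, which is not given and may differ between the groups.

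Exercise changed almost no single gene on either diet, and clock phase or pancreatic RNA in some arrays could hide an effect. With the clock covariate limma called 0 genes in LF+Ex vs LF, and without the 4 arrays with pancreatic transcripts it called 0, while the same setting called 240 in LF+CR vs LF. The clock covariate keeps all arrays, so its result argues against clock phase as the whole cause of the low count on the low-fat diet. The other setting removes an array from both groups, and the count was 0 without any single array of them. It also lowered HF vs LF from 127 to 13, so that it cannot decide about pancreatic RNA. LF 1 and LF+Ex 3 carried pancreatic transcripts and also had the highest clock differences of their groups (-1.88 and -0.66). The 2 tests are therefore not independent and cannot separate these traits. Neither test was set for the high-fat diet. Changes below the precision of 3 arrays stay open.

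Other splits of the same arrays were counted. For a pair of groups there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 127 and 2 genes in HF vs LF, 791 and 2 in LF+CR vs LF, 862 and 0 in HF+CR vs HF, 1 and 0 in LF+Ex vs LF, 1322 and 0 in LF+CR vs LF+Ex and 385 and 0 in HF+CR vs HF+Ex, and in each of these 1 split, the real one, reached the real count. In HF+Ex vs HF the real split gave 0, which all 10 splits reach by construction, and the highest other gave 14. For the calorie restriction by diet interaction 1 of 100 regroupings, the real one, gave 816 genes and the highest other 400. The regroupings mixed arrays of all groups in the contrast, also across the diets. They argue against a random assignment of arrays, but cannot tell an interaction from other group differences. For the exercise by diet interaction 7 of 100 gave as many as the real 1 and the highest other gave 417, so that chance cannot be excluded. These regroupings also moved arrays between the diets, so that the diet difference can enter the count. They do not test the interaction alone, and the source of the 417 genes was not identified.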

How the results depend on the processing

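The fits without 3 or 4 arrays and with the clock covariate were chosen after the data had been seen. The cause was not tested for any value below, apart from the smaller number of arrays in fits that leave some out. Of 4688 values of named genes under all alternatives, 4107 kept their direction and their side of the threshold, 581 kept the direction alone and 0 reversed. Of 2570 values of lists called with the preset correlation, 2376 kept both, 191 kept the direction alone and 3 reversed. These genes and lists had been chosen because they passed, and the alternatives use the same arrays. Few reversals are therefore expected from the choice itself and are no independent support. Signal over background limits the 3992 genes left out as dim.

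With 1 array left out, the number of genes changed ranged from 23 (without HF 1) to 200 (without HF 2) in HF vs LF, 446 (without LF+CR 1) to 915 (without LF+CR 3) in LF+CR vs LF, 284 (without HF 1) to 910 (without HF+CR 3) in HF+CR vs HF, 0 to 0 in LF+Ex vs LF, 0 to 1 (without HF+Ex 3) in HF+Ex vs HF, 801 (without LF+Ex 1) to 1272 (without LF+CR 3) in LF+CR vs LF+Ex, 125 (without HF+Ex 3) to 453 (without HF+CR 3) in HF+CR vs HF+Ex, 386 (without HF 1) to 1036 (without LF+CR 3) in the calorie restriction by diet interaction and 0 (without LF 1) to 1 (without LF+Ex 3) in the exercise by diet interaction. Array weights gave 988 in HF vs LF, 1435 in LF+CR vs LF, 2174 in HF+CR vs HF, 7 in LF+Ex vs LF, 2539 in LF+CR vs LF+Ex, 1067 in HF+CR vs HF+Ex, 1592 in the calorie restriction by diet interaction and 2 in the exercise by diet interaction. Fits of the compared groups only gave 60 in HF vs LF, 189 in LF+CR vs LF, 0 in LF+Ex vs LF, 532 in LF+CR vs LF+Ex and 93 in HF+CR vs HF+Ex. For LF+Ex vs LF the count was 0 with arrays centred on their median, 0 with the mean of probe sets and 2 with trend and robust. For the exercise by diet interaction it was 0 with quantile normalization and 0 with the mean of probe sets.

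The replicate numbers do not mark pairs: 9 of 45 pairs of arrays with the same number had deviations correlated above 0.1, and 2 of 18 arrays were closest to an array of their own number. With the replicate block the counts were 72 in HF vs LF, 632 in LF+CR vs LF, 649 in HF+CR vs HF, 1 in LF+Ex vs LF, 0 in HF+Ex vs HF, 1088 in LF+CR vs LF+Ex, 238 in HF+CR vs HF+Ex, 612 in the calorie restriction by diet interaction and 0 in the exercise by diet interaction.

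With 3 outlying arrays left out (LF+CR 2, HF 1, HF+Ex 3) the counts were 549 in HF+CR vs HF, 6 in LF+Ex vs LF, 191 in HF+CR vs HF+Ex and 371 in the calorie restriction by diet interaction. With 4 arrays with pancreatic transcripts left out (LF 1, LF+Ex 3, LF+CR 1, HF+Ex 1) they were 13 in HF vs LF, 240 in LF+CR vs LF, 517 in HF+CR vs HF, 0 in LF+Ex vs LF, 468 in LF+CR vs LF+Ex, 39 in HF+CR vs HF+Ex, 287 in the calorie restriction by diet interaction and 0 in the exercise by diet interaction. The clock covariate gave 231 in HF vs LF, 1374 in HF+CR vs HF, 0 in LF+Ex vs LF, 848 in HF+CR vs HF+Ex and 1391 in the calorie restriction by diet interaction.

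The list extracellular matrix and fibrosis, LF+CR vs LF, had a median of 0.10 and of -0.01 (-0.0130683) with 3 outlying arrays left out. The list pancreatic acinar cell, HF+Ex vs HF, had 0.65 and 0.0172 with 4 arrays left out, where the direction of the test changed. The list skeletal muscle, HF+Ex vs HF, had 0.21, and between -0.11 without HF+Ex 2 and 0.43 without HF+Ex 3. The similarity of fold changes, LF+CR vs LF with HF+CR vs HF, was 0.00413 with 3 outlying arrays left out, and the similarity of fold changes, LF+CR vs LF with LF+Ex vs LF, lay between -0.168 without LF+CR 2 and 0.0697 without LF 1, with 0.00927 without LF 3.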

Other observations

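The tests of the whole mRNA of Ptbp1, Sppl3 and Man2b1 and the bound of 2 times the dim threshold used there (195) were chosen after the values had been seen, as were these genes themselves.

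Single genes of further lists moved under calorie restriction, and none of these lists was called with an estimated correlation. In LF+CR vs LF, 3 of 25 endoplasmic reticulum chaperone genes rose, among them Calr (log2 0.40) and Pdia6 (log2 0.51), 6 when adjusted over the list alone (adjusted p = 0.478 with an estimated correlation), and 5 of 31 oxidative phosphorylation genes rose, such as Uqcrfs1 (log2 0.20) and Cycs (log2 0.35), 7 when adjusted over the list alone (adjusted p = 0.563 with an estimated correlation). In the growth hormone list 2 of 19 genes fell, Igfals, whose product carries IGF1 in blood (log2 -0.76), and Stat5a, the signal transducer (log2 -0.29), 6 when adjusted over the list alone (camera adjusted p = 0.0389, adjusted p = 0.528 with an estimated correlation). In HF+CR vs HF, 2 of 15 liver endothelial genes fell, Lyve1 (log2 -1.10) and Fcgr2b (log2 -0.31), 3 when adjusted over the list alone (adjusted p = 0.42 with an estimated correlation). Of 15 antioxidant genes 4 fell, including the lipid peroxide reductase gene Gpx4 (log2 -0.56), and 1 rose, Prdx4 (log2 0.38), with the same counts when adjusted over the list alone (adjusted p = 0.0854 with an estimated correlation). Of 21 NRF2 and glutathione genes 2 fell, Gsta2 (log2 -1.53) and Nqo1 (log2 -1.17), and 1 rose, with 13 lower and 1 higher when adjusted over the list alone (adjusted p = 0.42 with an estimated correlation).

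Single amino acid genes moved both ways in HF+CR vs HF: Tat, the tyrosine aminotransferase gene, rose by 0.82 and Mat1a, the methionine adenosyltransferase gene, fell by 0.38 on the log2 scale, with 3 of 22 urea cycle and amino acid genes higher and 2 lower, and the same counts when adjusted over the list alone (camera adjusted p = 0.974). Of 12 pericentral genes 1 rose and 2 fell, Glul (log2 -0.33) and Rhbg (log2 -0.54), both of ammonia handling, with 3 higher and 2 lower when adjusted over the list alone and a median of 0.12 (camera adjusted p = 0.995). The endotoxin binding protein gene Lbp fell by 0.59. Between LF+CR and LF+Ex the clock output gene Nfil3 had a log2 fold change of -1.31 and Bhlhe40 of 0.79, with 1 of 19 clock genes higher and 2 lower, 1 and 3 when adjusted over the list alone (camera adjusted p = 0.796). Nfil3 was at 412 ± 208 in LF+Ex, where log2 Arntl minus log2 Dbp was -0.66 on LF+Ex 3 against -3.28 and -3.62 on the other arrays. Apob, the structural protein gene of very-low-density lipoprotein, was lower by 1.04 in LF+CR than in LF+Ex, a log2 fold change of -1.04.

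In LF+CR vs LF single probe sets of Ptbp1, Sppl3 and Man2b1 fell while the others of these genes hardly moved. The probe set of Ptbp1, a splicing regulator gene, was at 3450 ± 573 in LF and 573 ± 184 in LF+CR (log2 -2.60, SE 0.291), that of Sppl3 at 1652 ± 275 and 470 ± 80.4 (log2 -1.78, SE 0.202), and that of Man2b1 at 3003 ± 331 and 1009 ± 88.6 (log2 -1.56, SE 0.153). For Ptbp1 and Sppl3 another probe set with a mean over 2 times the highest dim threshold did not fall (1046 ± 94.6 and 1137 ± 68.0 for Ptbp1, 220 ± 18.9 and 231 ± 5.66 for Sppl3, -3.94% of the chosen fall or less), which argues against a fall of the whole mRNA, while the other probe set of Man2b1 (1.11% of the chosen fall) lies too near background to tell. After removal of group means, the lowest of the 3 pairwise correlations across the 18 arrays was that of Ptbp1 and Sppl3, with r = 0.92 and Spearman's rho = 0.85 (permutation p = 1e-05 for r, the smallest that the permutations can give, and 5e-05 for rho, both two-sided, adjusted over the 3 pairs 1e-05 and 5e-05), and r = 0.89 without HF+Ex 3 and LF+CR 2. Without the 2 farthest arrays the lowest r was 0.863 (Sppl3 and Man2b1, without HF+Ex 3 and HF+Ex 2), below the 0.9 set beforehand for the 18 arrays. With all 18 arrays the lowest r exceeded 0.9, but no reference r was computed for probe sets of other genes. The correlations therefore cannot tell 1 transcript measured by all 3 probe sets from transcripts that vary together. Cross-hybridisation is a candidate explanation that stays open and was not tested, since probe sequences were not used.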
